A study of Rattus norvegicus with 60 samples.

How the data were processed

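Livers of male Sprague-Dawley rats, housed singly, were profiled by stranded polyA RNA sequencing with 1 library per rat. Rats received water or perfluorooctanoic acid (PFOA) by oral gavage at 1, 5 or 15 mg/kg per day for 7, 14 or 28 days, which makes 12 groups of 5 rats with a vehicle group at each of the 3 time points. The rats are described as 5 to 6 weeks old in the study design and as 7 to 8, 8 to 9 and 10 to 11 weeks old in the sample records of days 7, 14 and 28, and whether the first age is that at arrival or at the first dose is not stated. The deposited file holds raw read counts for 32883 Ensembl genes in 60 libraries, which were used without replicate pooling, and its values were checked to be whole numbers of at least 0. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.20.0.422, reads were trimmed with Trimmomatic 0.33 and aligned with STAR 2.5.2b to the rat build Rnor_6.0, and reads per gene were counted with featureCounts of Subread 1.6.0. Tool settings, annotation release and strand setting were not given in the sources used here. Total counts per library ran from 7965497 to 24770119 with a median of 12606152. The 10602 genes without a symbol held 1.39% of the reads, and 123 symbols were shared by several gene identifiers. The lowest chi-square per degree of freedom between libraries of a group was 18.3, so no library was a copy of another of its group. Libraries are numbered here from 1 to 5 within each group in the order of the sample records, since the labels give no replicate numbers.

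Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12167 genes. Counts were scaled by TMM, and a single group-means model over all 60 libraries was fitted with the robust quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with 48 residual degrees of freedom. Each dose was tested against the vehicle group of its day, 15 against 5 mg/kg within each day, the change of each dose's effect from day 7 to day 28 as an interaction, and the day 28 against the day 7 vehicle groups. P-values were two-sided and adjusted by Benjamini-Hochberg over the 12167 genes of a comparison, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale with the standard error (SE) taken as the fold change over the square root of F. Levels are CPM, counts scaled by library size and TMM, as mean and standard deviation (SD) of the 5 libraries of a group. Where a group held no count of a gene, the fold was bounded with 3 counts over the 5 libraries of the group, and with 1 to 3 counts the ratio is given with a 95% Poisson interval. These bounds and intervals cover counting error only.

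Before the data were examined, 39 gene lists were fixed with 756 members, covering metabolic and stress pathways, nuclear receptor targets, zonation and sex-biased genes and markers of the other cell types of liver. Of the members, 708 were found by symbol, 6 by an older or newer symbol and 42 were not found, and 644 memberships were among the genes tested. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the 39 lists of a comparison, and again with a correlation estimated for each list and with fry. A count "adjusted over the list alone" applies Benjamini-Hochberg to the members of that list. The genes named were also chosen by a rule fixed before the data were examined. It takes a fixed set of 21 genes, the called genes of largest change with mean CPM of at least 1 and no overlap between groups (10 in each direction at 15 mg/kg, 5 in each direction in other comparisons), and the 4 members of each list with the smallest p at 15 mg/kg on day 7 and on day 28.

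The alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-voom, a fit of only the libraries of the time point or groups compared, a fold change of at least 1.5 beside the adjusted p, and leaving out each library in turn. After the data were examined, a strong axis of variation within groups was found, and a library score was added as an alternative covariate. The score averages 500 genes along the first axis of the within-group residuals, which held 58.9% of the within-group variance, and the biological coefficient of variation of the model was 0.388 without the score and 0.196 with it. Another added alternative left out the 3 libraries with a score below -1.5. For each count of called genes, 100 splits of the same libraries into groups of the same sizes were refitted. The method was tested on simulated data with the spread of these libraries. In the comparison of 15 mg/kg with vehicle at day 28, 7.46% of genes with a 1.5-fold change, 38.8% with a 2-fold change and 75.8% with a 4-fold change were recovered, while 0.0334% of unchanged genes were called. Genes were drawn independently there, so the rate of false calls does not cover variation shared between genes. With a shared library axis and the spread left beside the score in the simulation, 26.9%, 70.1% and 87.9% were recovered without the score as covariate and 41.8%, 85.1% and 87.9% with it. The size of that axis was a set value, not fitted to these libraries, so these shares need not hold for them. Of 30 simulated lists of 20 genes, the 3 raised by 1.5-fold were called and none of the others were. Genome positions were not used here. Tables were handled with the data.table package (1.17.8), and figures were drawn with matplotlib 3.10.9 under Python 3.11.15.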

Results

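Liver RNA of 60 male rats was sequenced, with 5 rats in each of 12 groups that received water or PFOA, a perfluorinated surfactant, at 1, 5 or 15 mg/kg per day for 7, 14 or 28 days. The comparisons ask how the liver transcriptome responds to dose and to length of exposure. Total counts per library lay between 7965497 and 24770119, and 12167 genes were tested. The second principal component of log2 CPM (16.8% of variance) ordered the groups by dose. The first (49.1%) ran within groups: along it, cytosolic ribosomal protein genes went down (median within-group correlation with the library score -0.982, all 64 of 64 genes negative) while a list of genes of large proteins went up (median 0.947, 29 genes). The sign of the axis was set so that ribosomal protein genes go down. A mean score per library along this axis did not differ detectably between any dose and its vehicle group in exact permutation tests, where the smallest of 9 p-values was 0.103 (adjusted p = 0.5, n = 5 and 5). Differences from vehicle ran from -0.478 at 5 mg/kg and day 7 to 1.09 at 1 mg/kg and day 14, in SDs of the score over the 60 libraries. With 5 rats in each group such an imbalance can go undetected. Counts of called genes are given without the score and with it as a covariate. Genes said to rise or fall passed at an adjusted p under 0.05 by edgeR, and values after ± are SEs for log2 fold changes and SDs for levels.

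**Figure D1:**
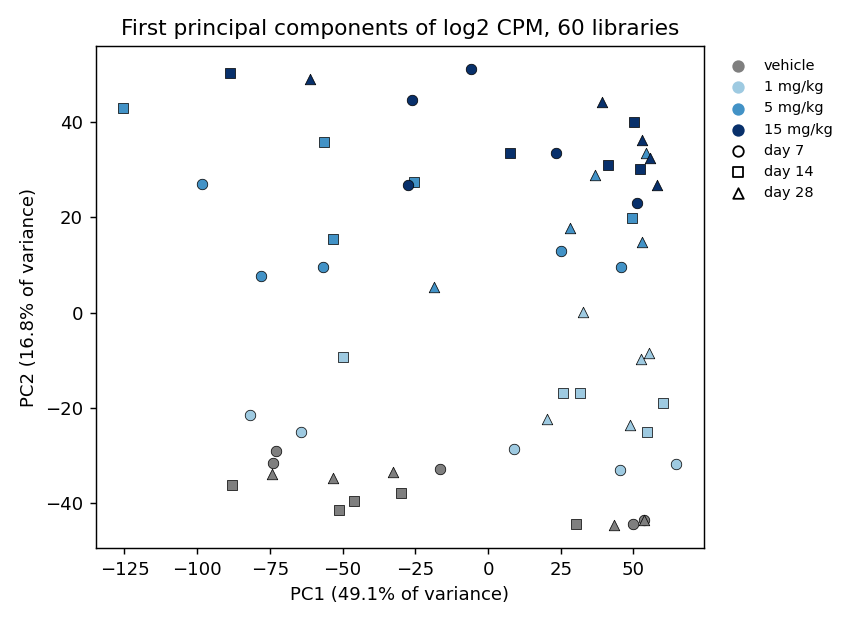
First and second principal components of log2 CPM, with 1 point for each of the 60 libraries, colour for dose and shape for day. Group means rise with dose along the second component (16.8% of variance), where some libraries of neighbouring doses overlap. Libraries of most groups spread widely along the first (49.1%), while those of 1 mg/kg at day 28 lay between 20.2 and 55.4 on it.

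After 7 days at 15 mg/kg, the liver carried far more transcripts for the breakdown of fatty acids. Acot1 (ENSRNOG00000055221), an acyl-CoA thioesterase, rose from 1.29 ± 1.37 to 758 ± 114 CPM (SD, n = 5), a log2 fold change of 9.22 ± 0.68 (adjusted p = 3.51e-15). Cpt1b, a carnitine palmitoyltransferase, rose by 6.67 ± 0.68 on the log2 scale, and Ehhadh (ENSRNOG00000001770), the bifunctional enzyme of peroxisomal β-oxidation, by 4.53 ± 0.27. Cyp4a1, a fatty acid ω-hydroxylase, rose by 4.0 ± 0.46, the pantetheinase Vnn1 by 3.22 ± 0.23, the isomerase Ech1 by 2.36 ± 0.14 and the kinase Pdk4, which restrains pyruvate oxidation, by 4.01 ± 0.55. Ucp3, a mitochondrial carrier with no read in the 5 vehicle libraries, was at least 138-fold higher. Of 24 peroxisomal fatty acid oxidation genes 12 rose, 1 fell and 11 did not pass (14 and 2 adjusted over the list alone, camera adjusted p = 4.73e-18). Of 19 mitochondrial fatty acid oxidation genes 14 rose and none fell (15 adjusted over the list alone, adjusted p = 1.66e-22). Among 27 other targets of PPARα, the nuclear receptor that governs these pathways, 22 rose and none fell (23 adjusted over the list alone, adjusted p = 1.65e-35). Hdc, which makes histamine, rose by 7.20 ± 0.76, and Asns, the asparagine synthetase, by 3.94 ± 0.42. Stac3, better known from muscle, fell by 3.69 on the log2 scale (SE 0.62).

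Sterol and lipoprotein genes went the other way at this dose and day. Idi1 (log2 fold change -2.87 ± 0.51) and Insig1 (-1.70 ± 0.36) fell. Of 25 cholesterol synthesis genes 10 fell and none rose (10 adjusted over the list alone, adjusted p = 1.56e-06 by camera, adjusted p = 0.127 with an estimated correlation). The sterol exporters Abcg5 (-3.65 ± 0.49) and Abcg8 (-4.36 ± 0.68), the apolipoprotein Apoa4 (-3.93 ± 0.52) and the cholesterol-esterifying enzyme Lcat (-1.13 ± 0.14) fell. Of 20 lipoprotein genes 8 fell and 2 rose (8 and 2 adjusted over the list alone, adjusted p = 0.000139). Among 21 genes of bile acid synthesis and transport 8 fell and 1 rose (8 and 2 adjusted over the list alone, adjusted p = 0.00154), and the single riser, the exporter Abcc3, was up by 4.08 ± 0.64. Lipogenic genes rose instead, with Srebf1, a master regulator of lipid synthesis, up by 2.29 ± 0.39, the desaturase Scd by 4.21 ± 0.65 and malic enzyme Me1 by 2.09 ± 0.30. Of 20 lipogenesis genes 7 rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.000642 by camera, adjusted p = 0.195 with an estimated correlation).

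Complement, coagulation and acute phase genes were lower as lists after 7 days at 15 mg/kg. The complement regulator Cfi (log2 fold change -1.56 ± 0.17) and the protease inhibitor Serpina1 (-0.97 ± 0.16) fell. Of 29 complement and coagulation genes 12 fell and none rose (13 adjusted over the list alone, camera adjusted p = 1.47e-08). Of 14 acute phase genes 6 fell and none rose (7 adjusted over the list alone, adjusted p = 0.000317). The deiodinase Dio1, which activates thyroid hormone (-2.71 ± 0.30), the glucose transporter Slc2a2 (-1.79 ± 0.31), the glycogen-targeting subunit Ppp1r3c (-2.64 ± 0.39) and the pericentral enzyme Cyp1a2 (-2.58 ± 0.43) fell. Cyp2b1, a classical target of the receptor CAR, rose by 4.22 ± 0.55. Of 18 CAR and PXR target genes 7 rose and 3 fell (7 and 5 adjusted over the list alone, adjusted p = 0.0139 by camera, adjusted p = 0.32 with an estimated correlation, adjusted p = 0.0656 by camera with the library score). Of 24 genes of the unfolded protein response 9 fell, among them the chaperone Calr (-0.94 ± 0.17), and 3 rose (14 and 3 adjusted over the list alone, adjusted p = 0.00808 by camera, adjusted p = 0.195 with an estimated correlation). The circadian repressor Nr1d1 rose by 4.36 ± 0.66 while Cry1 fell by 1.35 ± 0.25.

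All 12 genes encoded by mitochondrial DNA rose at 15 mg/kg and day 7, for example Mt-nd1 by 2.09 ± 0.37 on the log2 scale (12 adjusted over the list alone, adjusted p = 2.92e-11 by camera, adjusted p = 0.0703 with an estimated correlation). Their share of all reads was 8.50% ± 3.64 against 3.22% ± 1.77 in vehicle livers (SD, n = 5; exact permutation p = 0.0238, adjusted p = 0.0428 over 9 comparisons, a test chosen after the data were examined). Among the marker lists of other cell types, camera called the following 3 and none of the others. Of 15 stellate cell and fibroblast markers 3 fell and none rose (3 adjusted over the list alone, adjusted p = 0.00106), including Hgf (-1.55 ± 0.22). Of 12 Kupffer cell markers 2 fell (4 adjusted over the list alone, adjusted p = 0.000853 by camera, adjusted p = 0.3 with an estimated correlation). Of 6 erythroid markers 5 fell (5 adjusted over the list alone, adjusted p = 0.000423 by camera, adjusted p = 0.0745 with an estimated correlation), such as Ahsp, a haemoglobin chaperone, from 2.198 ± 2.13 to 0.240 ± 0.171 CPM (-3.12 ± 0.65). In total 824 genes were higher and 877 lower. All 33 called genes named for this comparison with a log2 fold change had all 5 treated libraries on the called side of the vehicle mean. The naming rule takes the genes of largest change only where groups do not overlap. Such tallies, here and below, were therefore set in advance for those genes. With the library score as covariate 2576 were higher and 2044 lower.

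At 15 mg/kg and day 14, fatty acid oxidation genes stayed high. Acot1 stood at 797 ± 224 CPM against 0.606 ± 0.542 in vehicle livers (SD, n = 5; log2 fold change 10.22 ± 0.71, adjusted p = 3.73e-16). Cpt1b rose by 7.31 ± 0.70 on the log2 scale, Ehhadh by 4.85 ± 0.27, Cyp4a1 by 4.07 ± 0.46, Pdk4 by 3.99 ± 0.55 and Cpt1a, the liver carnitine palmitoyltransferase, by 1.21 ± 0.32. Aqp3, a channel for water and glycerol with 3 reads over the 5 vehicle libraries, was higher by a ratio of 1553 (95% interval 531 to 7531), and Otop1, a proton channel with none, was at least 277.1-fold higher. In the peroxisomal list 14 of 24 genes rose and none fell (16 and 2 adjusted over the list alone, camera adjusted p = 1.57e-16). In the mitochondrial oxidation list 15 of 19 rose and none fell (15 adjusted over the list alone, adjusted p = 9.51e-21). Of the 27 other PPARα targets 23 rose and none fell (23 adjusted over the list alone, adjusted p = 8.36e-32). Chrna2, a nicotinic receptor subunit, rose by 7.84 ± 0.77, Hdc by 7.52 ± 0.77, Cyp2b1 by 4.53 ± 0.56 and Srebf1 by 2.14 ± 0.39. Of 20 lipogenesis genes 10 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.000115 by camera, adjusted p = 0.188 with an estimated correlation).

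At 15 mg/kg and day 14, Stac3 (log2 fold change -6.53 ± 0.72), Gimd1 (-6.66 ± 1.04), the acyltransferase Acnat2 (-5.27 ± 0.71), Abcg8 (-3.92 ± 0.66), the zinc finger gene Zfp189 (-3.88 ± 0.51), Dio1 (-2.28 ± 0.29) and the male-predominant Cyp2c11 (-0.85 ± 0.20) fell. Of 10 male-predominant genes 7 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.000656 by camera, adjusted p = 0.0571 with an estimated correlation). Of 20 lipoprotein genes 8 fell and 2 rose (10 and 2 adjusted over the list alone, adjusted p = 0.000284). Of 14 acute phase genes 7 fell and none rose (7 adjusted over the list alone, adjusted p = 0.00109). Cholesterol synthesis genes fell in 9 of 25 cases with none higher (11 adjusted over the list alone, adjusted p = 2.19e-05 by camera, adjusted p = 0.207 with an estimated correlation). Of complement and coagulation genes 15 of 29 fell, with none higher (16 adjusted over the list alone, adjusted p = 3.77e-07 by camera, adjusted p = 0.0714 with an estimated correlation). Proteasome subunits rose in 12 of 31 cases (13 adjusted over the list alone, adjusted p = 0.0036 by camera, adjusted p = 0.509 with an estimated correlation). Mitochondrially encoded genes rose in 11 of 12 cases (11 adjusted over the list alone, adjusted p = 2.1e-07 by camera, adjusted p = 0.199 with an estimated correlation). Their share of reads was 9.37% ± 1.63 against 3.42% ± 0.281 (SD, n = 5; exact permutation p = 0.00794, the smallest the design allows, adjusted p = 0.0238). Of the Kupffer cell markers 9 of 12 fell (10 adjusted over the list alone, adjusted p = 3.47e-06 by camera, adjusted p = 0.188 with an estimated correlation). In all, 1541 genes were higher and 1236 lower, and with the library score 2641 were higher and 2419 lower. All 5 treated libraries lay on the called side of the vehicle mean for each of the 17 called genes named with a log2 fold change.

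After 28 days at 15 mg/kg, the same pathways were raised. Acot1 reached 663 ± 162 CPM against 0.905 ± 1.32 (SD, n = 5; log2 fold change 9.43 ± 0.68, adjusted p = 1.93e-15) and Ehhadh 19440 ± 2802 against 752 ± 192 (4.69 ± 0.27). On the log2 scale Cpt1b rose by 7.26 ± 0.69, Cyp4a1 by 4.08 ± 0.46, Vnn1 by 3.76 ± 0.24, Pdk4 by 4.74 ± 0.57, the thioesterase Acot2 by 3.19 ± 0.24, Cpt1a by 1.54 ± 0.32 and Ech1 by 2.22 ± 0.14. Ucp3 was at least 593-fold higher, and Aqp3 higher by a ratio of 2080 (95% interval 712 to 10089). Of 24 peroxisomal fatty acid oxidation genes 13 rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 1.75e-16). Of 19 mitochondrial ones 15 rose and none fell (16 adjusted over the list alone, adjusted p = 7.14e-20). Of 27 other PPARα targets 23 rose and 1 fell (24 and 1 adjusted over the list alone, adjusted p = 2.48e-35). Lipogenic genes rose beside them: Srebf1 by 2.25 ± 0.39, the fatty acid synthase Fasn by 2.03 ± 0.56, the desaturases Scd2 and Fads2 by 4.58 ± 0.67 and 2.67 ± 0.37, and Me1 by 3.03 ± 0.31. The list had 12 of 20 members higher and 1 lower (12 and 1 adjusted over the list alone, adjusted p = 4.61e-07 by camera, adjusted p = 0.0523 with an estimated correlation). Drug-metabolism genes Cyp2b1 (4.66 ± 0.56), Aldh1a1 (3.19 ± 0.31) and Abcc3 (4.19 ± 0.67) rose. The CAR and PXR targets had 7 of 18 members higher and 3 lower (7 and 4 adjusted over the list alone, adjusted p = 0.00666 by camera, adjusted p = 0.303 with an estimated correlation). Asns rose from 0.890 ± 0.382 to 45.5 ± 16.4 CPM (5.61 ± 0.46), and the kinase-like Trib3 by 3.34 ± 0.59. Chrna2 and Slc5a8, a carrier of short fatty acids, rose by 8.55 ± 0.77 and 8.43 ± 0.76.

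Amino acid and periportal genes were lower at 15 mg/kg and day 28. Arg1 (log2 fold change -0.98 ± 0.19) and Ass1 (-1.28 ± 0.28) from the urea cycle, the glutaminase Gls2 (-1.49 ± 0.28), the proline oxidase Prodh1 (-1.68 ± 0.25) and Pck1, which controls glucose synthesis (-2.19 ± 0.47), fell. Of 32 amino acid catabolism and urea cycle genes 14 fell and 1 rose (18 and 2 adjusted over the list alone, adjusted p = 2.75e-06 by camera, adjusted p = 0.118 with an estimated correlation). Of 14 periportal genes 9 fell and none rose (10 and 1 adjusted over the list alone, adjusted p = 2.15e-05). Apoa4 (-3.44 ± 0.51), Apom (-2.10 ± 0.32) and Lcat (-1.07 ± 0.14) fell. Of the lipoprotein genes 7 of 20 were lower and 2 higher (8 and 2 adjusted over the list alone, adjusted p = 0.000156). Cfi (-1.41 ± 0.17) and C8b (-0.89 ± 0.12) fell, as did 14 of 29 complement and coagulation genes in all (14 adjusted over the list alone, adjusted p = 1.05e-07 by camera, adjusted p = 0.0523 with an estimated correlation). Of the acute phase genes 6 of 14 fell (6 adjusted over the list alone, adjusted p = 0.00113). Bile acid genes fell in 9 of 21 cases and rose in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.00427 by camera, adjusted p = 0.0558 with an estimated correlation). Stac3 (-6.61 ± 0.72), Acnat2 (-5.63 ± 0.72), Dio1 (-2.11 ± 0.29), Insig1 (-1.85 ± 0.36), Cry1 (-1.87 ± 0.25) and the cell cycle inhibitor Cdkn1a (-2.07 ± 0.48) fell, while Nr1d1 rose by 4.45 ± 0.63. Of 28 cell cycle genes 6 fell (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.0383 by camera, adjusted p = 0.51 with an estimated correlation, adjusted p = 0.133 by camera with the library score).

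Every one of the 12 mitochondrially encoded genes rose at 15 mg/kg and day 28, with Mt-nd1 up by 2.5 ± 0.38 and Mt-cyb by 1.79 ± 0.29 on the log2 scale (12 adjusted over the list alone, camera adjusted p = 3.78e-14). Their share of reads was 11.2% ± 1.72 against 3.47% ± 0.882 in vehicle livers (SD, n = 5; exact permutation p = 0.00794, the smallest the design allows, adjusted p = 0.0238). Of 12 Kupffer cell markers 4 fell (6 adjusted over the list alone, adjusted p = 0.00172 by camera, adjusted p = 0.383 with an estimated correlation). In all, 1082 genes were higher and 1011 lower at day 28, and with the library score 2236 were higher and 2066 lower. All 5 treated libraries lay on the called side of the vehicle mean for each of the 43 called genes named with a log2 fold change for this comparison, here or under the closing observations.

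**Figure D2:**
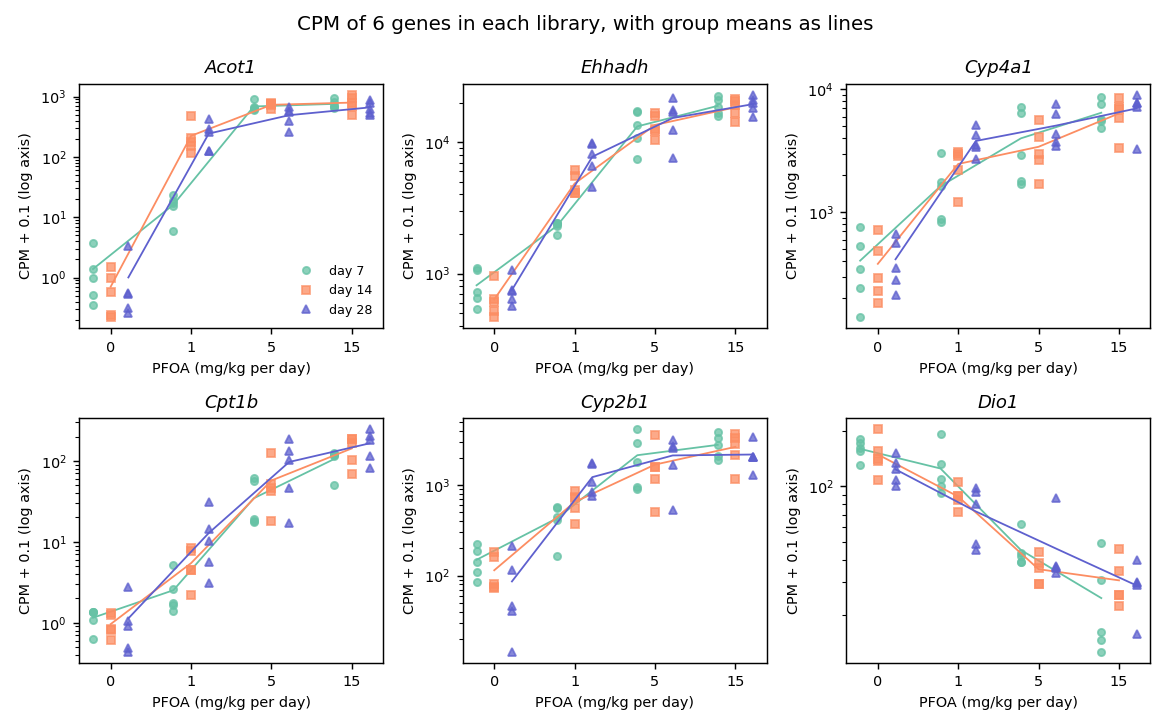
CPM plus 0.1 on a log axis for 6 genes in each of the 60 libraries against PFOA dose, with colour and shape for day and lines through the group means. Acot1 rises from 0.905 CPM in the day 28 vehicle group to 663 CPM at 15 mg/kg, while Dio1 falls with dose.

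Livers given 5 mg/kg for 7 days showed raised oxidation genes too. Acot1 stood at 687 ± 130 CPM against 1.29 ± 1.37 in vehicle livers (SD, n = 5; log2 fold change 9.07 ± 0.67, adjusted p = 7.1e-15). Ehhadh rose by 4.01 ± 0.26 on the log2 scale, Cyp4a1 by 3.31 ± 0.45, Cpt1b by 5.06 ± 0.64, Vnn1 by 3.01 ± 0.23, Cyp2b1 by 3.84 ± 0.54 and Dnajc5b by 5.36 ± 0.86, and Otop1 was at least 55.5-fold higher. Of the peroxisomal genes 12 of 24 rose (13 adjusted over the list alone, camera adjusted p = 8.27e-23). Of the mitochondrial oxidation genes 12 of 19 rose (15 adjusted over the list alone, adjusted p = 2.4e-29). Of the other PPARα targets 16 of 27 rose (19 adjusted over the list alone, adjusted p = 2.4e-29), with none lower in any of them. Aacs, which feeds ketone bodies into sterol and fat synthesis (-3.37 ± 0.48), Apoa4 (-3.08 ± 0.50), Abcg8 (-3.77 ± 0.65), Stac3 (-3.53 ± 0.61) and Dio1 (-1.83 ± 0.29) fell. None of the 25 cholesterol synthesis genes rose and 9 fell (14 adjusted over the list alone, adjusted p = 3.9e-10). Of 20 lipoprotein genes 3 fell and none rose (3 adjusted over the list alone, adjusted p = 0.000862). Also lower were 8 of 29 complement and coagulation genes (10 adjusted over the list alone, adjusted p = 1.86e-08) and 5 of 14 acute phase genes (5 adjusted over the list alone, adjusted p = 1.34e-05), with none higher. Of 24 unfolded protein response genes 6 fell and 1 rose (9 and 2 adjusted over the list alone, adjusted p = 3.89e-05). Altogether 398 genes were higher and 349 lower, and with the library score 1215 were higher and 1020 lower. For all 12 called genes named here with a log2 fold change the 5 treated libraries lay on the called side of the vehicle mean.

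With 14 days at 5 mg/kg, Acot1 stood at 732 ± 61.5 CPM against 0.606 ± 0.542 (SD, n = 5; log2 fold change 10.09 ± 0.71, adjusted p = 6.89e-16). Ehhadh rose by 4.40 ± 0.26 on the log2 scale, Cyp4a1 by 3.16 ± 0.45, Cpt1b by 5.99 ± 0.67, Hdc by 7.00 ± 0.75, Cyp2b1 by 3.88 ± 0.54 and Srebf1 by 1.55 ± 0.38, and Aqp3 was higher by a ratio of 750.2 (95% interval 256.4 to 3640). In the peroxisomal list 13 of 24 genes rose (15 and 2 lower adjusted over the list alone, camera adjusted p = 3.96e-21). In the mitochondrial oxidation list 15 of 19 rose (17 adjusted over the list alone, adjusted p = 2e-26). Among other PPARα targets 20 of 27 rose (23 and 1 lower adjusted over the list alone, adjusted p = 1.31e-34). Stac3 (-5.20 ± 0.67), Nfe2, a transcription factor of blood cells (-4.90 ± 0.72), Apoa4 (-3.89 ± 0.52) and Dio1 (-2.08 ± 0.29) fell. Cholesterol synthesis genes fell in 12 of 25 cases with none higher (15 adjusted over the list alone, adjusted p = 3.85e-11). Complement and coagulation genes fell in 11 of 29 cases (13 adjusted over the list alone, adjusted p = 1.13e-09) and acute phase genes in 5 of 14 (6 adjusted over the list alone, adjusted p = 9e-05). Lipoprotein genes fell in 5 of 20 cases with 2 higher (6 and 2 adjusted over the list alone, adjusted p = 0.000416). Of 12 Kupffer cell markers 4 fell (9 adjusted over the list alone, adjusted p = 2.16e-06 by camera, adjusted p = 0.134 with an estimated correlation). The share of reads from mitochondrially encoded genes was 4.58% ± 0.574 against 3.42% ± 0.281 (SD, n = 5; exact permutation p = 0.0159, adjusted p = 0.0358), while at day 7 the share had not passed at this dose (4.49% ± 1.5 against 3.22% ± 1.77, adjusted p = 0.246). In all, 666 genes were higher and 641 lower, and with the library score 1918 and 1833. Each of the 11 called genes named here with a log2 fold change had all 5 treated libraries on the called side of the vehicle mean.

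By day 28 at 5 mg/kg, Acot1 was at 493 ± 163 CPM against 0.905 ± 1.32 (SD, n = 5; log2 fold change 9.00 ± 0.67, adjusted p = 6.66e-15) and Ehhadh at 15250 ± 5372 against 752 ± 192 (4.34 ± 0.26). Cyp4a1 rose by 3.61 ± 0.45 on the log2 scale, Cpt1b by 6.49 ± 0.67, Cpt1a by 1.22 ± 0.32, Vnn1 by 3.47 ± 0.24, Cyp2b1 by 4.63 ± 0.56, Chrna2 by 8.02 ± 0.75, Slc5a8 by 7.15 ± 0.75 and Srebf1 by 1.70 ± 0.38. Ucp3 was at least 111-fold higher. Of the peroxisomal genes 13 of 24 rose (14 and 1 lower adjusted over the list alone, camera adjusted p = 5.69e-18). Of the mitochondrial oxidation genes 15 of 19 rose (16 adjusted over the list alone, adjusted p = 8e-22). Of the other PPARα targets 22 of 27 rose and 1 fell (23 and 1 adjusted over the list alone, adjusted p = 1.3e-34). Lipogenesis genes rose in 8 of 20 cases (12 adjusted over the list alone, adjusted p = 1.89e-06 by camera, adjusted p = 0.086 with an estimated correlation). Mitochondrially encoded genes rose in 8 of 12 (11 adjusted over the list alone, adjusted p = 3.02e-06 by camera, adjusted p = 0.254 with an estimated correlation), and their share of reads was 7.23% ± 1.89 against 3.47% ± 0.882 (SD, n = 5; exact permutation p = 0.00794, adjusted p = 0.0238). Stac3 (-6.40 ± 0.70), Hsd11b1, which regenerates active glucocorticoid (-4.2 ± 0.47), and Dio1 (-1.44 ± 0.28) fell, and Ltc4s, a leukotriene synthase with 2 reads over the treated libraries, was lower by a ratio of 134 (95% interval 36.5 to 1111). Lipoprotein genes fell in 6 of 20 cases with 1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.000283). Amino acid catabolism genes fell in 12 of 32 cases with 1 higher (17 and 2 adjusted over the list alone, adjusted p = 1.26e-05 by camera, adjusted p = 0.159 with an estimated correlation). Complement and coagulation genes fell in 8 of 29 (14 adjusted over the list alone, adjusted p = 1.89e-06 by camera, adjusted p = 0.086 with an estimated correlation), and periportal genes in 6 of 14 (10 and 1 higher adjusted over the list alone, adjusted p = 0.000245 by camera, adjusted p = 0.086 with an estimated correlation). In all, 685 genes were higher and 590 lower, 833 in total without treated library 3, and with the library score 1624 were higher and 1453 lower. The 5 treated libraries lay on the called side of the vehicle mean for each of the 13 called genes named here with a log2 fold change.

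At the lowest dose, 1 mg/kg, few genes had passed by day 7. Acot1 rose from 1.29 ± 1.37 to 16.1 ± 6.46 CPM (SD, n = 5; log2 fold change 3.65 ± 0.55, adjusted p = 0.000227), Ehhadh by 1.5 ± 0.23 on the log2 scale (adjusted p = 0.000263) and Vnn1 by 1.37 ± 0.22 (adjusted p = 0.000263), each in 5 of 5 libraries. The protease gene Tmprss2 fell by 1.22 ± 0.19 (adjusted p = 0.000263), also in 5 of 5, a call lost when only the libraries of day 7 were fitted (-1.20, adjusted p = 0.126). Of 24 peroxisomal fatty acid oxidation genes 2 rose (3 adjusted over the list alone, camera adjusted p = 1.34e-07). Of 19 mitochondrial ones 1 rose (4 adjusted over the list alone, adjusted p = 7.61e-10). Of 27 other PPARα targets 3 rose (5 adjusted over the list alone, adjusted p = 1.74e-07 by camera, adjusted p = 0.0503 by fry), with none lower. Mitochondrially encoded genes shifted up as a list by camera (adjusted p = 1.36e-15, by fry adjusted p = 0.0503) with a median of 0.63, none of 12 passing over all genes and 8 adjusted over the list alone. Their share of reads at 1 mg/kg did not pass on any day (5.47%, 4.44% and 4.70% at days 7, 14 and 28 against 3.22%, 3.42% and 3.47%, adjusted p = 0.0816, 0.125 and 0.0816). In all, 11 genes were higher and 3 lower, with 7 in total without vehicle library 3 and 8 without vehicle library 4. The fit with the library score gave 104 higher and 74 lower.

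By day 14 at 1 mg/kg, Acot1 had reached 224 ± 142 CPM against 0.606 ± 0.542 (SD, n = 5; log2 fold change 8.38 ± 0.67, adjusted p = 3.25e-13). Ehhadh rose by 2.93 ± 0.25 on the log2 scale, Cyp4a1 by 2.70 ± 0.44, Vnn1 by 1.42 ± 0.22, Hdc by 4.87 ± 0.69 and Cyp2b1 by 2.5 ± 0.51. Of the peroxisomal genes 8 of 24 rose (12 adjusted over the list alone, camera adjusted p = 5.58e-11). Of the mitochondrial oxidation genes 11 of 19 rose (15 adjusted over the list alone, adjusted p = 1.45e-13). Of the other PPARα targets 13 of 27 rose (17 adjusted over the list alone, adjusted p = 4.7e-14). Idi1 (-3.37 ± 0.52), Stac3 (-2.89 ± 0.58) and Nfe2 (-3.14 ± 0.58) fell. Cholesterol synthesis genes fell in 11 of 25 cases with none higher (11 adjusted over the list alone, adjusted p = 2.95e-07 by camera, adjusted p = 0.262 with an estimated correlation). Unfolded protein response genes fell in 7 of 24 cases with 1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.0221 by camera, adjusted p = 0.5 with an estimated correlation). The 9 called genes named here had all 5 treated libraries on the called side of the vehicle mean. In all, 458 genes were higher and 359 lower, and with the library score 807 and 742, among them 83.6% of the genes called without it. Single libraries weighed heavily on this total of 817: it was 494, 1278, 290 and 244 without vehicle libraries 1, 2, 3 and 4, 328, 422 and 1377 without treated libraries 1, 3 and 4, and 2.5e+02 without treated library 2.

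Animals on 1 mg/kg for 28 days had Acot1 at 244 ± 126 CPM against 0.905 ± 1.32 (SD, n = 5; log2 fold change 7.98 ± 0.65, adjusted p = 2.16e-13) and Ehhadh at 7747 ± 2195 against 752 ± 192 (3.36 ± 0.25). Vnn1 rose by 2.97 ± 0.23 on the log2 scale, Cyp4a1 by 3.20 ± 0.45, Cpt1b by 3.57 ± 0.60, Cyp2b1 by 3.83 ± 0.54, Hdc by 5.21 ± 0.69 and Chrna2 by 5.33 ± 0.69, and Aqp3 was higher by a ratio of 311.96 (95% interval 107 to 1515). Of the peroxisomal genes 9 of 24 rose (11 and 1 lower adjusted over the list alone, camera adjusted p = 3.16e-13). Of the mitochondrial oxidation genes 11 of 19 rose (16 adjusted over the list alone, adjusted p = 1.3e-15). Of the other PPARα targets 13 of 27 rose and 1 fell (20 and 1 adjusted over the list alone, adjusted p = 3.28e-18). The faller was the hydroxylase Cyp4a8 (-3.45 ± 0.68). CAR and PXR targets rose in 4 of 18 cases (8 adjusted over the list alone, adjusted p = 1.39e-06 by camera, adjusted p = 0.0573 with an estimated correlation). Hsd11b1 (-2.57 ± 0.43) and Aacs (-2.37 ± 0.46) fell. Cholesterol synthesis genes fell in 3 of 25 cases (3 adjusted over the list alone, adjusted p = 0.024 by camera, adjusted p = 0.861 with an estimated correlation). All 11 called genes named here with a log2 fold change had the 5 treated libraries on the called side of the vehicle mean. In sum, 225 genes were higher and 168 lower, a total of 393 that was 200, 235 and 202 without vehicle library 1, vehicle library 5 and treated library 1, and with the library score 491 were higher and 414 lower.

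**Figure D3:**
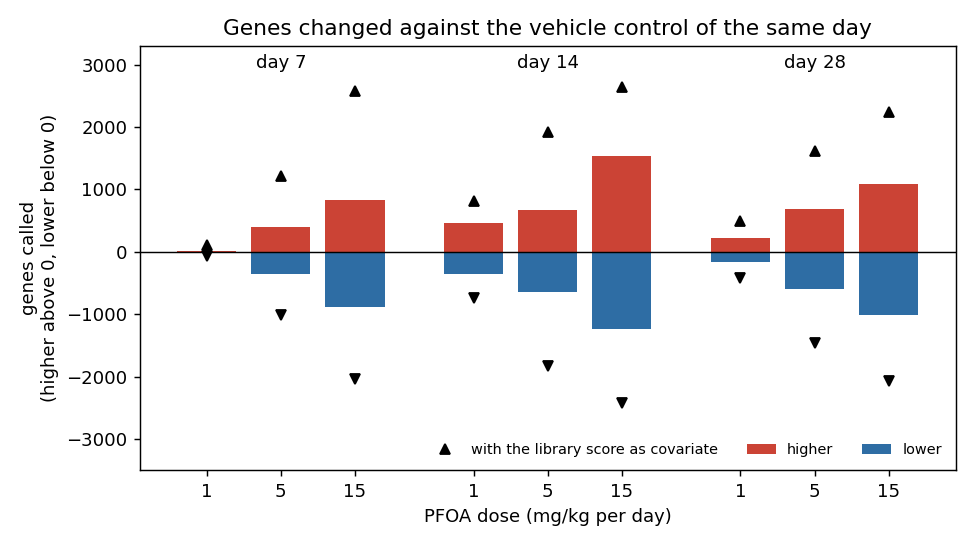
Number of genes called higher (bars above 0) or lower (bars below 0) than the vehicle group of the same day, by PFOA dose, with triangles for the counts with the library score as covariate. Calls at 15 mg/kg number 824 higher and 877 lower at day 7, 1541 and 1236 at day 14, and 1082 and 1011 at day 28.

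**Figure D4:**
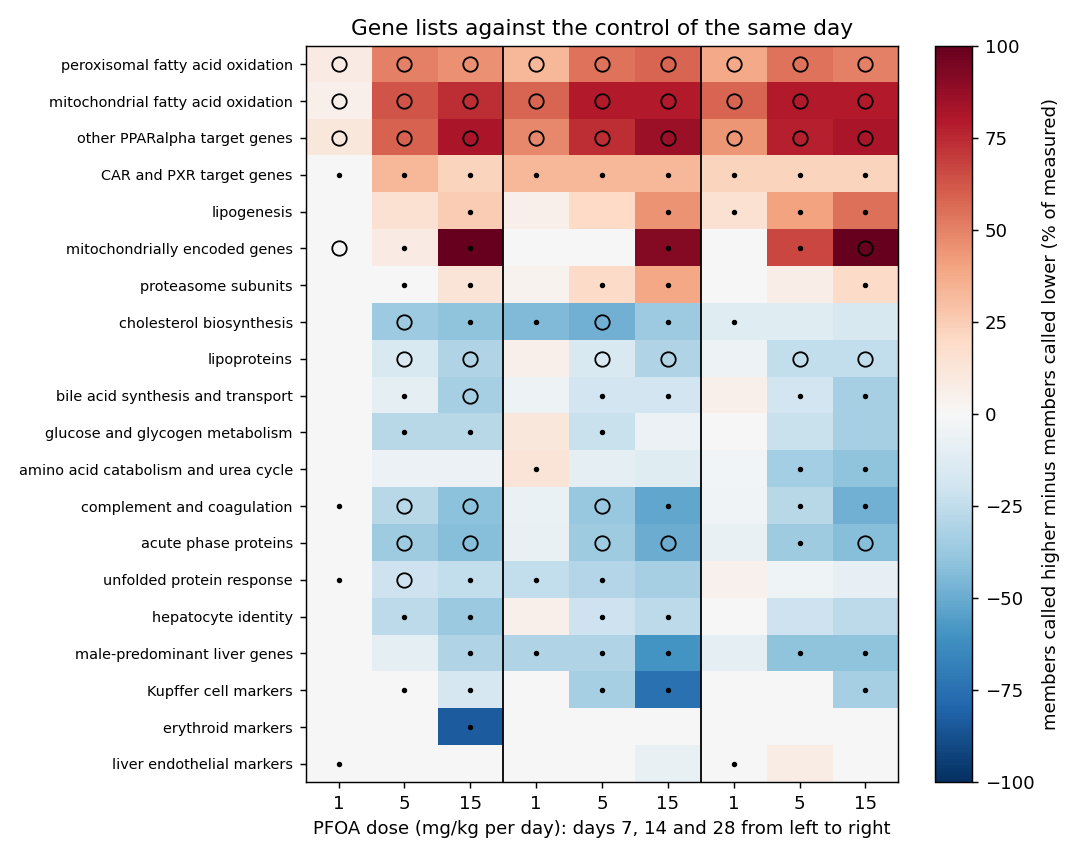
Members called higher minus members called lower, as a percentage of the measured members of 20 gene lists, by dose and day. Small dots mark lists called by camera with its preset correlation, and open circles those also called with an estimated correlation, as the fatty acid oxidation and PPARα target lists are at every dose and day.

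To ask whether the highest dose added to the middle one, 15 mg/kg was compared with 5 mg/kg. At day 7 Ucp3 was higher by 3.62 ± 0.63 on the log2 scale (adjusted p = 0.00786), the fatty acid binding protein gene Fabp3 by 3.44 ± 0.65 (adjusted p = 0.00786) and Asns by 1.72 ± 0.38 (adjusted p = 0.031), while the cell division gene Cdca2 was lower (-1.81 ± 0.39, adjusted p = 0.031), each in 5 of 5 libraries. With only the libraries of day 7, the calls of Ucp3 (adjusted p = 0.0612) and Asns (0.0679) were lost. Of 27 other PPARα targets 2 were higher (4 adjusted over the list alone, adjusted p = 1.58e-07 by camera, adjusted p = 0.0912 with an estimated correlation). Of 12 mitochondrially encoded genes 2 were higher (10 adjusted over the list alone, adjusted p = 7.77e-10 by camera, adjusted p = 0.19 with an estimated correlation). Of 28 cell cycle genes 1 was lower (14 adjusted over the list alone, adjusted p = 7.77e-10 by camera, adjusted p = 0.0912 with an estimated correlation). Of 6 erythroid markers 2 were lower (5 adjusted over the list alone, adjusted p = 5.75e-05 by camera, adjusted p = 0.1 with an estimated correlation). In all, 20 genes were higher and 20 lower, and with the library score 489 and 260. The total of 40 was 19, 164, 10 and 0 without 5 mg/kg libraries 1, 2, 3 and 5 and 18, 96, 5 and 3 without 15 mg/kg libraries 1, 3, 4 and 5. The calls of Asns and Cdca2 were also lost without 5 mg/kg libraries 1 and 3 and 15 mg/kg libraries 1 and 5, and that of Asns without 15 mg/kg library 4, with adjusted p between 0.0553 and 0.144.

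At day 14 edgeR called 0 genes between 15 and 5 mg/kg, with 1458 at an unadjusted p under 0.05, DESeq2 called 37 and limma-voom 0. With the library score edgeR called 2 higher and 7 lower. Mitochondrially encoded genes were nonetheless higher as a list, with a median of 0.88 and 11 of 12 passing adjusted over the list alone (adjusted p = 2.02e-09 by camera, adjusted p = 0.471 with an estimated correlation). Lipogenesis genes had a median of 0.76 (1 of 20 adjusted over the list alone, adjusted p = 0.000159 by camera, adjusted p = 0.471 with an estimated correlation). Of 27 other PPARα targets 3 passed adjusted over the list alone (adjusted p = 0.000312 by camera, adjusted p = 0.471 with an estimated correlation). Leaving out 5 mg/kg libraries 2, 3, 4 and 5 gave 1, 13, 3 and 1 genes, and leaving out 15 mg/kg libraries 2 and 3 gave 3 and 11.

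At day 28 only 5 genes separated the upper doses by edgeR, and 4 of them were chosen for mention after their values were seen. Fgf13 was higher at 15 than at 5 mg/kg by 3.39 ± 0.63 on the log2 scale, Fabp3 by 3.22 ± 0.62, the sterol exporter Abcg1 by 2.27 ± 0.44 (each adjusted p = 0.013) and the clock output gene Dbp by 2.10 ± 0.42 (adjusted p = 0.0201), and Acnat2 was lower (-3.36 ± 0.65, adjusted p = 0.013). All 5 libraries at 15 mg/kg lay on the called side of the 5 mg/kg mean for 4 of these genes and 4 of 5 for Fgf13. With only the libraries of day 28, all 5 calls were lost (adjusted p from 0.0943 to 0.299), as were those of Fgf13 (0.236) and Acnat2 (0.0599) by limma-voom. Mitochondrially encoded genes were higher as a list with a median of 0.68 (none of 12 passing over all genes, 11 adjusted over the list alone, camera adjusted p = 3.87e-23, fry adjusted p = 0.117), and 1 of 27 other PPARα targets was higher (2 adjusted over the list alone, adjusted p = 2.3e-09 by camera, adjusted p = 0.117 by fry). The 8 female-predominant genes were lower as a list with a median of -0.95 though none passed singly (0 adjusted over the list alone, adjusted p = 4.28e-05 by camera, adjusted p = 0.118 by fry). The library score brought 11 genes higher and 4 lower. The count was 3, 1 and 0 without 5 mg/kg libraries 1, 4 and 5, and 3, 2 and 3 without 15 mg/kg libraries 2, 3 and 5. Without 15 mg/kg library 3 the difference of Fgf13 was 2.13 (adjusted p = 0.466 by edgeR). Calls were also lost without 5 mg/kg library 3 (Abcg1, adjusted p = 0.0533, and Dbp, 0.0789), 5 mg/kg library 2 (Dbp, 0.0732), 15 mg/kg library 4 (Dbp, 0.0557) and 15 mg/kg library 1 (Acnat2, 0.0936).

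Whether an effect changed between day 7 and day 28 was tested as an interaction. At 1 mg/kg the fold change against vehicle was higher at day 28 than at day 7 for 7 genes and lower for none. Asns differed by 4.53 ± 0.59 on the log2 scale (adjusted p = 5.77e-06), going from 2.36 ± 0.892 CPM at day 7, against 2.86 ± 0.912 in vehicle, to 17.6 ± 7.54 at day 28, against 0.890 ± 0.382 (SD, n = 5). Acot1 differed by 4.33 ± 0.75 (adjusted p = 0.00242), Ehhadh by 1.86 ± 0.33 (adjusted p = 0.00242), Vnn1 by 1.6 ± 0.31 (adjusted p = 0.0106), Aldh1a1 by 2.06 ± 0.40 (adjusted p = 0.0106), the serine synthesis gene Psat1 by 2.11 ± 0.45 (adjusted p = 0.0336) and the hydrolase Abhd3 by 7.43 ± 1.46 (adjusted p = 0.0109). A lower vehicle level at day 28 than at day 7 is part of these differences, with log2 fold changes between the vehicle groups of -1.65 for Asns, -0.40 for Acot1, -0.12 for Ehhadh, -0.83 for Vnn1, -1.44 for Aldh1a1, -0.93 for Psat1 and -3.03 for Abhd3. Of these, only that of Aldh1a1 passed between the vehicle groups. That of Acot1 depends on single libraries, with 3.63 CPM in day 7 vehicle library 1 and 3.26 CPM in day 28 vehicle library 5. With only the groups compared, edgeR called 1 gene, and the calls of all but Asns were lost (adjusted p from 0.147 for Ehhadh to 0.776 for Aldh1a1), as were those of Abhd3 (0.818) and Psat1 (0.214) by limma-voom. The peroxisomal list differed upwards with a median of 0.44 (1 of 24 genes, 8 adjusted over the list alone, camera adjusted p = 5.43e-06). So did the mitochondrial oxidation list with a median of 0.38 (0 of 19, 4 adjusted over the list alone, adjusted p = 4.21e-06) and the other PPARα targets, with 2 of 27 genes (10 and 1 lower adjusted over the list alone, adjusted p = 2.36e-11). Without day 7 vehicle library 1 the count was 3 and the calls of Acot1 (adjusted p = 0.055), Aldh1a1 (0.055), Vnn1 (0.0567) and Psat1 (0.135) were lost. The call of Abhd3 was lost without day 7 vehicle library 5 (0.828) or day 28 treated library 5 (0.41), and that of Psat1 also without day 7 vehicle library 5, day 7 treated libraries 1, 4 and 5, any one of the day 28 vehicle libraries, or day 28 treated libraries 3 and 4 (0.0522 to 0.291). Fitted with the library score, the difference was upwards for 22 genes and downwards for 1.

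At 5 mg/kg edgeR called only the effect on Asns as different between the days, by 3.12 ± 0.57 on the log2 scale (adjusted p = 0.0171), going from 13.4 ± 5.88 CPM at day 7, against 2.86 ± 0.912 in vehicle, to 37.5 ± 13.9 at day 28, against 0.890 ± 0.382 (SD, n = 5), so that a lower vehicle level is part of the difference. That call was lost with the library score, where the difference was 2.76 (adjusted p = 0.0962) and 1 other gene was called, and by limma-voom (adjusted p = 0.0850). It was also lost without day 7 vehicle libraries 2 and 5, 5 mg/kg libraries 3 and 5 of day 7, vehicle libraries 1 and 2 of day 28, or 5 mg/kg libraries 2 and 3 of day 28 (adjusted p between 0.0638 and 0.0814, count 0 each), while leaving out day 7 vehicle libraries 3 and 4 gave 2 and 7 genes. DESeq2 called 4 genes upwards and 8 downwards, limma-voom 0 and 2, and a fit of only the groups compared 1 and 1. Lipogenesis genes differed upwards as a list with a median of 0.80 (0 of 20 genes, 7 adjusted over the list alone, adjusted p = 0.00037 by camera, adjusted p = 0.408 with an estimated correlation), and cell cycle genes downwards with a median of -0.94 (0 of 28, 8 adjusted over the list alone, adjusted p = 2.25e-05 by camera, adjusted p = 0.408 with an estimated correlation).

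At 15 mg/kg edgeR called 0 genes whose effect differed between day 7 and day 28, with 335 at an unadjusted p under 0.05. DESeq2 called 5 and limma-voom 1. Amino acid catabolism genes differed downwards as a list (median -0.46, 0 of 32 genes, 0 adjusted over the list alone, adjusted p = 3.65e-10 by camera, adjusted p = 0.0984 with an estimated correlation). Cholesterol synthesis genes differed upwards (median 0.47, 0 of 25 genes, 1 adjusted over the list alone, adjusted p = 1.39e-06 by camera, adjusted p = 0.246 with an estimated correlation), as did erythroid markers (median 2.01, 0 of 6 genes, 0 adjusted over the list alone, adjusted p = 1.74e-05 by camera, adjusted p = 0.0984 with an estimated correlation). Both of these lists had lower medians in the vehicle group at day 28 than at day 7, which is part of their differences. Leaving out 15 mg/kg library 1 of day 7, vehicle library 2 of day 28 or vehicle library 4 of day 28 gave 1 gene each, as did the library score.

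Between the vehicle groups of day 7 and day 28, a span in which the rats aged, edgeR called 5 genes. Age, time point and any processing batch of a time point cannot be told apart in this comparison. Sparc, a matrix protein gene, was lower at day 28 (-0.87 ± 0.17 on the log2 scale, adjusted p = 0.0202), as were the lipoxygenase gene Alox15 (-3.77 ± 0.75, adjusted p = 0.0202) and Aldh1a1 (-1.44 ± 0.29, adjusted p = 0.0202), while Sdr16c6 was higher (6.12 ± 1.27, adjusted p = 0.031). AABR07037307.1 was higher by a ratio of 220 (95% interval 39.1 to 8724) over a single read at day 7 (adjusted p = 0.00172). Aldh1a1 and these last 2 genes were chosen after their values were seen. All 5 day 28 libraries lay on the called side of the day 7 mean for 4 genes and 4 of 5 for Sdr16c6. With only the vehicle libraries of these days, all 5 calls were lost (adjusted p from 0.0856 to 1), as were those of Alox15 (0.150) and Sdr16c6 (1.00) by limma-voom. Erythroid markers were lower as a list at day 28 (median -1.84, 0 of 6 genes, 4 adjusted over the list alone, adjusted p = 3.01e-06 by camera, adjusted p = 0.0521 with an estimated correlation). Also lower were cholesterol synthesis genes (median -0.38, 0 of 25 genes, 2 adjusted over the list alone, adjusted p = 1.36e-10 by camera, adjusted p = 0.0797 with an estimated correlation). The total of 5 genes became 1 without day 7 library 1, day 28 library 1 or day 28 library 3, and 67 higher and 38 lower with the library score. AABR07037307.1 alone kept its call when any single library was left out. Alox15 also lost it without day 28 libraries 2 and 4 (adjusted p = 0.0688 and 0.099), Sparc without day 28 library 4 (0.0924), Aldh1a1 without day 7 library 2 and day 28 library 5 (0.0618 and 0.0569) and Sdr16c6 without any one of the day 7 libraries (0.0574 to 0.163).

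Responses at different days were set against each other across the 12167 genes, which are not independent replicates. At 15 mg/kg the log2 fold changes of days 14 and 28 had Pearson's r = 0.874 and Spearman's rho = 0.835, those of days 7 and 14 r = 0.827 and rho = 0.765, and those of days 7 and 28 r = 0.812 and rho = 0.721. Between days 14 and 28, 1588 genes were called in the same direction and 0 in opposite ones, where 240 shared calls would fall together if calls were independent, and between days 7 and 28 the numbers were 1200, 0 and 146. At 5 mg/kg r was 0.735 for days 7 and 14, 0.621 for days 14 and 28 and 0.411 for days 7 and 28 (rho 0.651, 0.383 and 0.114), and 416 genes were called the same way at days 7 and 28 with 0 in opposite directions and 39.3 by chance. With the library score the value for days 7 and 28 was 0.717, and leaving out 1 library at a time gave 0.268 to 0.554. From such refits the jackknife SE of r was 0.148 for days 7 and 14, 0.270 for days 14 and 28 and 0.387 for days 7 and 28. At 1 mg/kg r was 0.195 for days 7 and 14, 0.401 for days 7 and 28 and 0.688 for days 14 and 28 (rho 0.145, 0.408 and 0.681), and the last was 0.389 with the library score. Leaving out 1 library at a time, the value for days 7 and 28 ranged from 0.123 to 0.593. The jackknife SE of r was 0.615 for days 7 and 14, 0.580 for days 7 and 28 and 0.143 for days 14 and 28. The value for days 7 and 14 changed sign without day 7 vehicle library 3 (-0.0217), day 7 vehicle library 4 (-0.0694) or day 7 treated library 5 (-0.116).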

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

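The tests of the library axis and of the low dose at day 7 were chosen after the results were seen, as was the library score and so the search for distant libraries along it. The search in total counts, the rule for single genes, the interactions and the refitted splits without the score were fixed before the data were examined. Which single genes and groups were searched was set by the levels picked for the text, with the results in view. In 10 of 68 groups of 5 libraries, the gap between an extreme library and its nearest neighbour was a larger share of the group's range than Dixon's 95% critical value. By that rule chance picks about 1 in 20 groups of normally distributed values, which low CPM need not be. Total counts set apart vehicle library 1 of day 14 (gap share 0.728), with 17682900 counts against 7965500 to 10608700 in the other 4. The library score set apart 15 mg/kg library 2 of day 28 (0.844), at -1.36 against 0.636 to 1.00. Acot1 set apart 4 libraries. They were 5 mg/kg library 1 of day 7 (0.774, 914 CPM against 591 to 664), 1 mg/kg library 4 of day 14 (0.758, 471 CPM against 118 to 204), 5 mg/kg library 3 of day 14 (0.725, 626 CPM against 738 to 780) and vehicle library 5 of day 28 (0.904, 3.26 CPM against 0.157 to 0.454). Asns set apart 15 mg/kg library 5 of day 28 (0.770, 74.1 CPM against 33.0 to 42.5). Abhd3 set apart vehicle library 5 of day 7 (0.934, 8.28 CPM against 0.124 to 0.660), vehicle library 3 of day 28 (0.772, 0.550 CPM against 0.114 to 0.213) and 1 mg/kg library 5 of day 28 (0.974, 44.2 CPM against 0.695 to 1.83).

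Effects that differed between day 7 and day 28 by the interaction test were those of Abhd3 (7.43), Asns (4.53), Acot1 (4.33), Psat1 (2.11), Aldh1a1 (2.06), Ehhadh (1.86) and Vnn1 (1.6) at 1 mg/kg and of Asns (3.12) at 5 mg/kg, all on the log2 scale with adjusted p under 0.05. Abhd3 rests on single libraries: without day 7 vehicle library 5 its difference was 4.88 (adjusted p = 0.828), and without day 28 treated library 5 it was 4.19 (adjusted p = 0.41). Of the lists described in the results, those that differed by camera had medians of 0.445 for peroxisomal fatty acid oxidation, 0.381 for mitochondrial fatty acid oxidation and 0.706 for other PPARα targets at 1 mg/kg. At 5 mg/kg the medians were 0.80 for lipogenesis and -0.944 for cell cycle genes (each adjusted p = 0.408 with an estimated correlation). At 15 mg/kg they were -0.457 for amino acid catabolism and the urea cycle (adjusted p = 0.0984 with an estimated correlation), 0.467 for cholesterol synthesis (adjusted p = 0.246 with an estimated correlation) and 2.01 for erythroid markers (adjusted p = 0.0984 with an estimated correlation). A lower vehicle level at day 28 is part of the differences of cholesterol synthesis genes and erythroid markers.

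The axis within groups may reflect RNA integrity or fragment length: the median within-group correlation with the library score was higher by 1.93 for 29 genes of large proteins than for 28 genes of small mitochondrial subunits. Those subunits share a function, and nuclear-encoded oxidative phosphorylation genes lay at the same end (median -0.963). A low value for them was likely in advance. The difference therefore does not tell length or integrity from variation shared by such genes. The score followed the log of total counts (r = 0.458, permutation p = 0.0007, n = 60), so depth was not excluded, and thinning was chosen after that. With every library thinned to 7965497 counts, the thinned score still followed the full score within groups (r = 0.99995). Thinning keeps the composition of each library, so this shows only that counting noise does not make the axis. The link with depth stays open. Marker lists of other cell types lay on opposite sides, 1.42 apart between endothelial markers (0.815) and T and NK cell markers (-0.609). Kupffer cell (-0.508) and erythroid (-0.468) markers were negative too. Stellate cell (0.168) and cholangiocyte (0.396) markers and hepatocyte identity genes (0.609) were positive. The other cell types thus did not move together, but a shift of immune and blood cells against the rest was not tested. Cell composition stays open. Dose could not be told from chance, at 17.8% of score variance between dose groups within time points (permutation p = 0.346).

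The low count at 1 mg/kg and day 7, 14 genes against 817 and 393 at days 14 and 28, could be a matter of library spread, of depth or of an effect that grows with exposure. With the library score as covariate the counts were 178, 1549 and 905, and the smaller of the later counts was still 5.08 times the first. With all libraries thinned to the smallest total they were 15, 675 and 352, a ratio of 23.5. Spread and depth are therefore argued against as the whole cause, and a part played by spread stays open. Among the 2777 genes called at 15 mg/kg and day 14, the median signed log2 fold change at 1 mg/kg was 0.0789 at day 7 and 0.390 at day 28. That ratio of 0.202 (0.241 with the score) points to an effect that is smaller at day 7, though vehicle and treated animals of each day are different animals. The spread of this ratio over libraries was not measured. The interaction at 1 mg/kg called only 7 genes, a count that 6 of 100 splits reached, so the ratio carries limited weight.

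Counts of called genes were compared with 100 splits of the same libraries, the real one included. Splits with at least as many calls numbered 1 for 15 mg/kg at day 7 (1701 genes, highest other 533), 1 for 5 mg/kg at day 14 (1307, 726), 1 for 1 mg/kg at day 28 (393, 37), 2 for 5 mg/kg at day 28 (1275, 1516), 2 for 1 mg/kg at day 14 (817, 4805), 2 for 15 mg/kg at day 14 (2777, 5700), 3 for 1 mg/kg at day 7 (14, 5878) and 4 for 15 mg/kg at day 28 (2093, 4230). They numbered 2 for 15 against 5 mg/kg at day 7 (40, 3088), 2 at day 28 (5, 5) and 4 for the vehicle groups (5, 5268). Chance could not be excluded for 5 mg/kg at day 7 (6 splits, 747, 7186) or for the interactions at 1 mg/kg (6, 7, 6977) and 5 mg/kg (11, 1, 3733). Part of the gene-wise spread was estimated once, with the real groups, and kept for every split, which can favour the real one. The numbers were also not adjusted over the comparisons. Low numbers of splits therefore do not exclude chance by themselves. For 15 against 5 mg/kg at day 14 and the interaction at 15 mg/kg edgeR called 0 genes in the real split, a count that all 100 splits reach, so these splits decide nothing (highest other 2 and 1). Splits that call so many genes point to structure among the samples. Once the score is fitted, only the real split reached its count in all 9 comparisons with vehicle. The score was derived once, with the real groups, and kept for every split. This can favour the real split, so its lead does not exclude chance. Other splits still called many genes, and their highest count was lower than without the score for 1 mg/kg at day 7 (40, real 178), 5 mg/kg at day 7 (822, real 2235), 1 mg/kg at day 14 (1114, real 1549), 15 mg/kg at day 14 (1951, real 5060) and 15 mg/kg at day 28 (1986, real 4302). It was higher for 15 mg/kg at day 7 (2253, real 4620), 5 mg/kg at day 14 (1875, real 3751), 1 mg/kg at day 28 (199, real 905) and 5 mg/kg at day 28 (1518, real 3077). Fitted so, 15 against 5 mg/kg at days 7, 14 and 28 gave 3, 1 and 2 splits, the vehicle groups 1, and the interactions at 1, 5 and 15 mg/kg 5, 18 and 9.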

How the results depend on the processing

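Of the alternatives, the library score and the fit without the 3 libraries of lowest score were chosen after the data were examined, and the others before. The 175 named values, 174 of them under DESeq2, kept their direction in each refit that was run. All 175 values were called in the main fit and many were chosen for large changes, so a kept direction was likely in advance. They lost their call in 1 case with DESeq2 size factors, 7 with limma-voom, 19 with only the libraries compared, 1 with the library score and none without the filter on low counts or, for 174 values, with DESeq2. The 19 were Tmprss2 at 1 mg/kg and day 7, Ucp3 and Asns for 15 against 5 mg/kg at day 7, the 5 genes named at day 28, the interactions at 1 mg/kg other than that of Asns, and the 5 genes of the vehicle groups (adjusted p from 0.0612 to 1). By limma-voom they were Fgf13 and Acnat2 for 15 against 5 mg/kg at day 28, the interactions of Abhd3 and Psat1 at 1 mg/kg and of Asns at 5 mg/kg, and Alox15 and Sdr16c6 of the vehicle groups. Leaving out 1 library at a time ended the call of 19 named values in 82 of 1830 refits. Asking for a fold change of at least 1.5 moved no count beyond 1.5 times. Of 212 list calls in 624 tests, 55 were kept with an estimated correlation, and fry called 146. The following values moved by more than 1.5 times, and the cause was not tested.

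Fitted with the library score, counts against vehicle at 1, 5 and 15 mg/kg were 178, 2235 and 4620 at day 7, 1549, 3751 and 5060 at day 14, and 905, 3077 and 4302 at day 28. For 15 against 5 mg/kg they were 749, 9 and 15, for the interactions at 1 and 15 mg/kg 23 and 1, and for the vehicle groups 105. Without the libraries of lowest score, 1 mg/kg at day 7 gave 28, 15 against 5 mg/kg at day 7 gave 26 and the interaction at 15 mg/kg 1. DESeq2 called 42, 1300 and 641 genes at 1 mg/kg on days 7, 14 and 28, 131, 37 and 9 for 15 against 5 mg/kg, 17, 12 and 5 for the interactions and 13 for the vehicle groups. With only the libraries compared, 1, 5 and 15 mg/kg at day 7 gave 3, 415 and 1069, 1 mg/kg at day 14 gave 335, 15 against 5 mg/kg gave 2, 2 and 0, the interactions at 1 and 5 mg/kg 1 and 2 and the vehicle groups 0. Without the filter, 1 mg/kg gave 369 at day 14 and 2.6e+02 at day 28, and 15 against 5 mg/kg gave 16 at day 7 and 3 at day 14. By limma-voom, 15 against 5 mg/kg at day 7 gave 21, the interactions at 5 and 15 mg/kg 2 and 1 and the vehicle groups 3. With DESeq2 size factors, 15 against 5 mg/kg at day 14 gave 2.

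Leaving out 1 library at a time gave 7 to 21, 244 to 1377 and 200 to 494 genes at 1 mg/kg on days 7, 14 and 28, 833 to 1624 at 5 mg/kg and day 28, 0 to 164, 0 to 13 and 0 to 6 for 15 against 5 mg/kg, 3 to 8, 0 to 7 and 0 to 1 for the interactions and 1 to 7 for the vehicle groups. The correlation between days 14 and 28 at 1 mg/kg was 0.389 with the library score. That between days 7 and 14 at 1 mg/kg ranged from -0.116 to 0.404 and was -0.0217, -0.0694 and -0.116 without day 7 vehicle libraries 3 and 4 and day 7 treated library 5. That between days 7 and 28 ranged from 0.123 to 0.593 at 1 mg/kg and from 0.268 to 0.554 at 5 mg/kg, where it was 0.717 with the library score. In simulated data with the spread of these libraries, 38.8% of 2-fold changes were recovered, so changes of that size can go uncalled. With a simulated library axis, whose size was set and not fitted, 70.1% were recovered (85.1% with the score as covariate).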

Other observations

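All tests of this part were chosen after the results were seen. No list of amino acid synthesis genes was fixed, and the 4 genes here were brought together after their values were seen. At 15 mg/kg and day 28, Phgdh and Psat1 of serine synthesis rose by 4.76 ± 0.73 and 2.65 ± 0.33 on the log2 scale, and Slc3a2, the heavy chain of amino acid exchangers, by 2.5 ± 0.39. Asns rose by 5.61 ± 0.46 (each adjusted p under 0.05 by edgeR, 5 of 5 libraries above the vehicle mean).

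A stress response through the transcription factor ATF4 could raise these genes. Another 32 ATF4 targets, set down before their values were looked at, had a median of 0.584 at 15 mg/kg and day 28, with 13 higher and 0 lower (p = 0.102 with an estimated correlation) and with 16 higher and 2 lower with the library score. At days 7 and 14 of this dose 10 and 18 of the 32 were higher and 0 lower (p = 0.0832 and 0.0503 with an estimated correlation), which leaves the question open. Stress of the endoplasmic reticulum that raises chaperone genes is argued against at days 7 and 14. There 7 and 10 of 28 chaperone and degradation genes were lower and 0 higher, with medians of -0.570 and -0.439 (p = 0.00547 and 0.0195 with an estimated correlation). Unfolded protein response genes had already been seen to fall at day 7, so this list was no unseen test. Stress without a rise of chaperone genes is not addressed by it. At day 28 stress of the endoplasmic reticulum is left open: 4 of these genes were lower and 0 higher, with a median of -0.305 (p = 0.0936 with an estimated correlation). With the library score 15 were lower and 1 higher.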
